A study of Mus musculus with 8 samples.

How the data were processed

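Total RNA of sorted ES cells, of a control culture and of 3 embryonic tissues was labelled with Cy3 from 50 ng and hybridized to Agilent mouse expression arrays, 1 array for each of the 8 groups, per the labels. RNA of 3 sets of experiments was pooled before labelling, so no p-value here measures the spread of repeated cultures. Per the file headers, the authors read the arrays with Agilent Feature Extraction 10.7.3.1, while the processing notes name version 9.1 and limma without a version, and the headers place the probes on the mm9 mouse genome build. The deposited scanner tables give intensity for each spot, background-subtracted and detrended within the array by the authors and not scaled between arrays, along with calls such as well above background. The deposited value table holds log2 values of 55682 probes that the authors normalized between arrays. Its column medians were 6.36 for RAX-negative and 6.39 for RAX-positive cells after activin, 6.37 and 6.40 after SAG, 6.37 for the Wi control, 6.37 for cortex, 6.36 for diencephalon/hypothalamus and 6.36 for eye. Sorted values differed between its columns by a mean of 0.0139, close to quantile normalization, and each column had a correlation of 0.992 to 0.999 with the log2 of the unsubtracted median signal. The scale of that table is therefore log2 and it is not centred on 0 or turned into ratios, but the background step and the offset used are not given in the sources used here.

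Each array held 62976 spots, of which 3671 were controls. The 59305 other spots stood for 55681 probes, 432 of them spotted more than once, and the log2 signals of repeated spots were averaged after spots called outliers by the scanner software were removed (136 to 307 spots for each array). There were 0 saturated spots, and 262 probes had outlier spots alone and were left out. Signal differed in depth among the arrays, with 59.5% to 79.3% of spots well above background, and the median standard deviation of repeated probes was 0.054 to 0.070 log2. The spike-in slope was outside the range of the scanner software for RAX-positive cells after activin, both SAG populations and diencephalon/hypothalamus. The spike-in detection limit (log10 concentration) was 1.77 for RAX-positive cells after activin and 0.81 to 1.21 on the other arrays. Signals were taken to log2 after division by the 75th percentile of their array. Probes were named through the RefSeq accession of the array annotation (28354 probes) or else by the name in the files (27327 probes), which gave 34634 gene names, and 11157 genes had more than 1 probe. A gene was read from its probe with the highest mean over the 8 arrays, and other probes of a gene can differ. Of 160 top-ranked results in the comparisons of 2 arrays, 39 had more than 1 probe, and in 20 of these the probes were more than 2 apart in log2. Probe positions are those of the files, 1-based on mm9, and the part of the gene that a probe covers was not annotated.

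Groups were compared as pairs of arrays, RAX-positive against RAX-negative cells within each treatment, activin against SAG within each gate, and each sorted population against the Wi control, with the rule of size given in the report and no p-value. A gene counts as detected in a pair where the array with its higher level was well above background. A gene well above background on 1 array alone is thus kept where it is higher there and left out where it is lower there. The measurement error of each signal was taken from the scanner software. Calls of the same sign in 2 comparisons are set beside the number for independent calls. The gate contrasts after activin and after SAG use different arrays of the same slide, and the contrasts of activin against SAG use those same 4 arrays again. The gate and the added factor were fitted together on the 4 sorted arrays with limma 3.58.1 in R 4.3.3 (empirical Bayes moderated t, Benjamini-Hochberg adjustment, genes well above background on at least 2 arrays), with a prior of 2.25 degrees of freedom. With 1 residual degree of freedom the number of arrays limits precision. The error of the fit is the difference between the gate effects after activin and after SAG. A gate effect that depends on the added factor therefore counts as error, in both contrasts of the model. RAX-positive arrays were all in column 1 of the slide and RAX-negative arrays in column 2, so the gate cannot be told from the slide column. Both activin arrays were at position 1 of their column and both SAG arrays at position 2. The added factor therefore cannot be told from the slide position. The Wi control was alone on another slide, and 7 arrays shared slide 1.

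For 31 fixed lists of marker, pathway and control genes, the median log2 difference of the detected genes was taken relative to that of all detected genes. It was compared with 10000 random lists drawn from the same 20 bins of mean expression, and a bootstrap of 1000 draws over the genes of the list gave a 95% range. A list outside the central 95% of random lists is called apart from them. On simulated data, lists of 15 genes fell outside that range in 3% of 100 draws without a shift and in 99% with a log2 shift of 1. The simulation shuffled the differences over genes and drew genes at random. It therefore does not cover lists whose genes vary together. The limma model was tested on simulated data with 200 changed genes. Sizes of 1, 2 and 3 were planned, and 4 and 6 were added after 0% were recovered at the planned sizes, with 68% recovered and 7 false calls at 6. Olfactory and vomeronasal receptor genes, 1359 in number, served as a group with little reason to be expressed in these cells. For the tissues, a gene was assigned to the one in which its log2 difference was at least 2 over each other tissue. Similarity was the Pearson correlation of log2 levels over the 4302 genes whose levels spanned at least 2 in log2 among the 3 tissues, with each gene centred on its mean over the cultures and, apart from that, on its mean over the tissues, and without centring.

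Genes are named in the report by a rule. In each comparison these are the 10 highest and 10 lowest by bounded difference among those that passed the rule of size, and for the gate and the added factor across both settings the 10 with the largest smaller difference. For the tissues they are those with the largest smaller difference over the others. Members of the fixed lists may be named with any list they belong to. The exceptions are clone-like, predicted, receptor and accession-like names, and names of near copies are marked where given. Some genes that the rule names are not reported here. As alternatives, normexp background correction with an offset of 50, median scaling, quantile scaling, the authors' values, the mean over probes, and outlier spots kept were run, along with other limits of size (log2 2, 3 times the error), tissue limits (log2 1, top 100 genes), limits on background, and limma with trend, robust variance, all 8 arrays or an adjusted p of 0.1. The comparisons against the bounded difference and without the Wi control in the similarity were chosen after the data were seen. Other software was python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.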

Results

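Gene expression was measured on 8 single-colour Agilent mouse arrays, 1 for each group. The sorted cells came from K/l-EB5, a male mouse embryonic stem (ES) cell line that carries green fluorescent protein (GFP) at Rax, a homeobox gene of the early eye field and hypothalamus. The cells were neuralized and given IWR-1-endo, an inhibitor of Wnt signalling (Wi), at 5 µM from day 3. Activin A at 10 ng/ml, a ligand of the Activin/Nodal pathway, or SAG at 100 nM, an agonist of the Hedgehog pathway, was added 12 h later. At 10 days in vitro the RAX::GFP-positive and RAX::GFP-negative cells of each treatment were sorted, and are called RAX-positive and RAX-negative here. The Wi control was E14Tg2A, another male ES cell line, grown to the same day with the inhibitor alone, with no sort named. Cortex, diencephalon with hypothalamus, and eye were dissected from 3 mouse embryos at E12.5. The RNA of 3 sets of experiments was pooled before labelling, so each group had 1 array and no replicate.

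The share of spots well above background was 79.3% on the array of RAX-positive cells after activin and 59.5% on that of RAX-negative cells after activin. It was 70.5% and 66.4% for the RAX-positive and RAX-negative cells after SAG, 67.5% for the Wi control, 62.5% for cortex, 73.0% for diencephalon/hypothalamus and 75.0% for eye. A gene is called higher or lower between 2 arrays where the brighter spot was well above background and the log2 difference was at least 1, which is a rule of size and not a test. Where the dimmer array was near its background, its level was set to no less than the lowest signal well above background on that array, and the fold is given as "at least". The measurement error of a log2 difference, from the Agilent error model, had a median of 0.20, or 1.15-fold, over genes well above background on both arrays. It was larger near background, for example 1.06 for Foxd3 between gates after activin. That error covers the reading of an array and not the spread between cultures. Gene groups are fixed lists chosen before the data were examined. The median log2 difference of a list is given relative to the median of all detected genes in that comparison, a choice made after the scaling shifts were seen. It is set beside the central 95% of 10000 random lists of like expression, as a description.

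**Figure D1:**
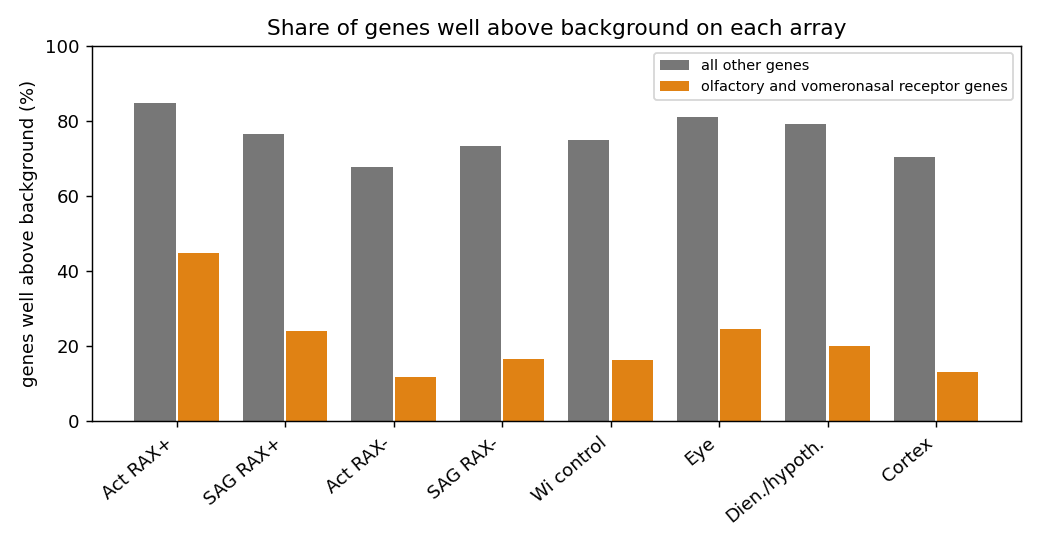
Percent of genes well above background on each of the 8 arrays. Orange bars are olfactory and vomeronasal receptor genes, and grey bars are all other genes.

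RAX-positive cells after activin expressed the eye-field transcription factors at higher levels than the RAX-negative cells of the same cultures. Six6 was 12.98-fold higher, Nr2e1 11.5-fold, Lhx2 7.50-fold, Tbx3 7.02-fold, Pax6 5.91-fold and Six3 5.87-fold. These genes set up the optic vesicle and keep retinal progenitors dividing. Rax was 8.87-fold higher (mm9 probe position chromosome 18, 66094331 to 66094390), and since the cells were sorted on it, that checks the labels and is no finding. Of the eye-field list, 13 of 17 detected genes were higher and Fgf15 was lower, by 2.48-fold, with a relative median of 2.36 (bootstrap 95% range over genes 1.02 to 2.96), above the random lists. Mab21l1, needed for eye growth, was 10.97-fold higher, and Hmx1, of the eye and ear, 17.8-fold. Vax1 and Pax2, of the optic stalk and ventral retina, were 9.95-fold and 4.49-fold higher, while their list of optic cup and stalk genes had 3 of 11 higher and lay within the random lists. The hypothalamic transcription factor genes Fezf1, Nkx2-1 and Nkx2-4 were 5.79-fold, 3.96-fold and 3.22-fold higher. The hypothalamus list, which shares Rax, Six6 and Tbx3 with the eye-field list, had 11 higher and 5 lower of 26, a relative median of 0.42 with a bootstrap 95% range of -0.50 to 1.496 that includes 0. Among the largest differences were Sowaha (28.2-fold higher, with its 2 probes at 2.44 and 4.82 in log2), the muscle gene Neb (at least 25.4-fold), the copper carrier Cp (24.4-fold), the lens crystallin genes Cryge (at least 19.6-fold) and Crybb1 (15.5-fold), Mlc1 (17.2-fold) and Neurog3 (16.1-fold). The lens and surface ectoderm list had 6 higher and 6 lower of 22, within the random lists.

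Pluripotency genes were lower in the RAX-positive cells after activin. Pou5f1 was 176-fold lower (mm9 probe position chromosome 17, 35647280 to 35647340), Dppa5a 83.3-fold, Fgf4 61.6-fold, Zfp42 52.6-fold, L1td1 48.3-fold and Utf1 35.7-fold, and Pou5f1 has a near copy, Pou5f1-rs4, that makes the source of its signal uncertain. Of that list, 16 of 19 genes were lower and 0 higher, with a relative median of -3.85. Fgf5, a gene of the epiblast, was 128-fold lower, Foxd3 at least 105-fold, Tcl1 at least 65.2-fold, Trap1a 82.8-fold, Calcr 76.4-fold, Ldoc1 73.3-fold and the hypothalamic hormone gene Trh 71.9-fold. Genes of mesoderm and endoderm went the same way, with Sox17 41.3-fold, Cer1 21.7-fold, Foxa2 12.4-fold and Gata6 9.87-fold lower, and 11 of 16 of their list lower at a relative median of -2.95. The neural crest and mesenchyme list had 11 of 19 lower at -2.03, among them the collagen gene Col3a1 (36.0-fold) and Postn (at least 39.0-fold). Direct targets of Activin/Nodal signalling were lower as well, with Lefty2 at 14.8-fold, Lefty1 at 10.68-fold and Nodal at 8.11-fold, and 8 of 19 of that list lower, a relative median of -1.14, with Cer1 shared with the germ-layer list and Tdgf1 with the pluripotency list. The Wnt target list had 2 higher and 8 lower of 18 (-0.86), with Dkk1 lower by 10.1-fold and Axin2 by 3.30-fold. Pan-neural progenitor genes were higher, with Sox1 at 4.39-fold and Hes5 at 4.00-fold, and 7 of 16 higher against 2 lower.

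Of 28922 genes detected in this comparison, 6623 were higher and 1824 lower in the RAX-positive cells by the rule of size, or 78.4% higher. Among the 22191 genes well above background on both arrays, 1288 were higher and 1438 lower. The split moved with the scaling and with the background step. Median scaling gave 5441 higher and 2659 lower, and quantile scaling 4051 and 2585. The authors' values gave 1825 and 1960, and normexp background 695 and 1199. On the array of RAX-positive cells after activin, 44.7% of 1359 olfactory and vomeronasal receptor genes were well above background, against 24.7% on the array with the next largest share. That array also had the highest spike-in detection limit, and a spike-in slope outside the range of the scanner software, as had both SAG populations.

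After SAG the RAX-positive cells again had more of the eye-field factors than the RAX-negative cells, and lower neuronal genes. Tbx3 was 13.4-fold higher (mm9 probe position chromosome 5, 120134511 to 120134570), Six3 5.78-fold, Rax 5.30-fold, Six6 4.96-fold and Lhx2 3.29-fold. The growth factor genes Fgf9 and Fgf10 were 9.68-fold and 9.27-fold higher, and Fzd5, a Wnt receptor needed in the eye field, 10.69-fold. Stac was 12.7-fold higher, Cd55b at least 8.71-fold and Maf 6.11-fold. The eye-field list had 6 higher and 2 lower of 16, a relative median of 0.36 (bootstrap 95% range -0.42 to 1.64), above the random lists. Pax6 and Nr2e1 were not called, and Mab21l1 was lower by at least 5.23-fold and Aldh1a1 by 2.52-fold. Of the Hedgehog pathway genes, Hhip was 5.87-fold, Gli1 2.63-fold and Ptch1 2.62-fold higher. The list of Hedgehog targets as a whole, which also holds Nkx2-1 and Nkx2-2 from the hypothalamus list, had 5 higher and 7 lower of 16 at -0.25, within the random lists.

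The genes that were lower after SAG included those of differentiating neurons. Neurog2, a proneural gene, was 105-fold lower, Nrn1 131-fold (its 2 probes at -7.03 and -2.78 in log2), Gap43 7.94-fold and Dcx 5.35-fold. Markers of inhibitory transmission, Gad1 (12.7-fold), Slc32a1 (7.88-fold) and Gad2 (5.49-fold), were lower, as were the glutamate transporter gene Slc17a6 (5.61-fold) and the dopamine synthesis gene Th (6.44-fold). Of the neurotransmitter list, 9 of 12 were lower and 0 higher, at a relative median of -2.55, and of the neuron list 10 of 20 at -1.10. The ventral telencephalon list was lower for 12 of 16 genes (-2.50), with Lhx8 at 18.9-fold and Dlx1 at 5.48-fold. In the hypothalamus list 4 were higher and 10 lower of 25, a relative median of -0.45, with Sim1 lower by at least 51.7-fold and Trh by 25.3-fold. Mesenchymal genes were lower, Foxf2 by at least 115-fold, Col3a1 by 105-fold and Postn by at least 32.9-fold, with 14 of 18 of the neural crest and mesenchyme list (-1.84). The GABA receptor gene Gabrr3 was at least 145-fold lower, Ldoc1 at least 118-fold and Vtn 63.3-fold. Pluripotency genes were lower by less than after activin, 9 of 18 at -1.13, with Zfp42 at 27.0-fold and Pou5f1 at 2.33-fold. Cell-cycle genes were not called in this comparison, yet their relative median of 0.44 lay above the random lists.

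By the rule of size 1983 genes were higher and 2761 lower of 26600 detected, or 41.8% higher. Median scaling gave 2857 higher and 2345 lower, and normexp background 451 and 1251.

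Across both treatments, 682 genes were higher and 663 lower in the RAX-positive cells, against 302 and 133 for independent calls. Ranked by the smaller difference, Fgf9 (10.0-fold after activin and 9.68-fold after SAG) and Tbx3 led the higher genes, with Six3os1 (9.90-fold and 6.04-fold), which lies beside Six3, the melatonin-receptor relative Gpr50 (7.48-fold and 4.37-fold) and Neurog3 (16.1-fold and 4.19-fold) among them. The lower genes were led by Ldoc1 and Serpinb9g, which has close copies, and held the placental gene Plac1 (31.0-fold and 57.3-fold). Another 724 genes were higher after activin and lower after SAG, against 409 for independent calls, and 77 the other way round, against 98.3. These counts were made in the main setting alone. The number for independent calls takes every detected gene as equally likely to be called. The larger share of receptor genes above background, given earlier, concerns the activin RAX-positive array that enters the 682 and the 724.

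An additive limma model of gate and treatment takes the difference between the gate effects after activin and after SAG as its error. On the 4 sorted arrays that model, which leaves 1 residual degree of freedom, tested 26473 genes. For the gate it called 0 genes higher and 0 lower at an adjusted p of 0.05, with a smallest adjusted p of 0.482. At an unadjusted p of 0.05 there were 1122 higher and 867 lower genes, and the other settings run gave between 0 and 176 higher and between 0 and 523 lower at the adjusted level. Fgf9 had a limma log2 difference of 3.30 (standard error 0.29, adjusted p 0.482). Adjusted over the list alone, 5 eye-field genes passed (Rax, Six3, Six6, Lhx2 and Tbx3), 7 of the hypothalamus list, 7 of the pluripotency list and 7 of the neural crest and mesenchyme list, against 0 of each over all genes tested. Rax, Six6 and Tbx3 count in both the eye-field and the hypothalamus number, and Rax, the sort marker, is no finding there either. The hypothalamus genes that passed went both ways, with Trh and Foxb1 lower in RAX-positive cells. Genes of the neuron, Hedgehog target, and mesoderm and endoderm lists passed as well, so passing was not particular to the lists above. The hypothalamus list had a limma median of -0.04 across treatments, opposite in sign to its relative median after activin. When 200 genes were given a log2 change of 4 in simulated arrays the model recovered 0% of them, and at 6 it recovered 68%, so a count of 0 does not mean that nothing differed.

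**Figure D2:**
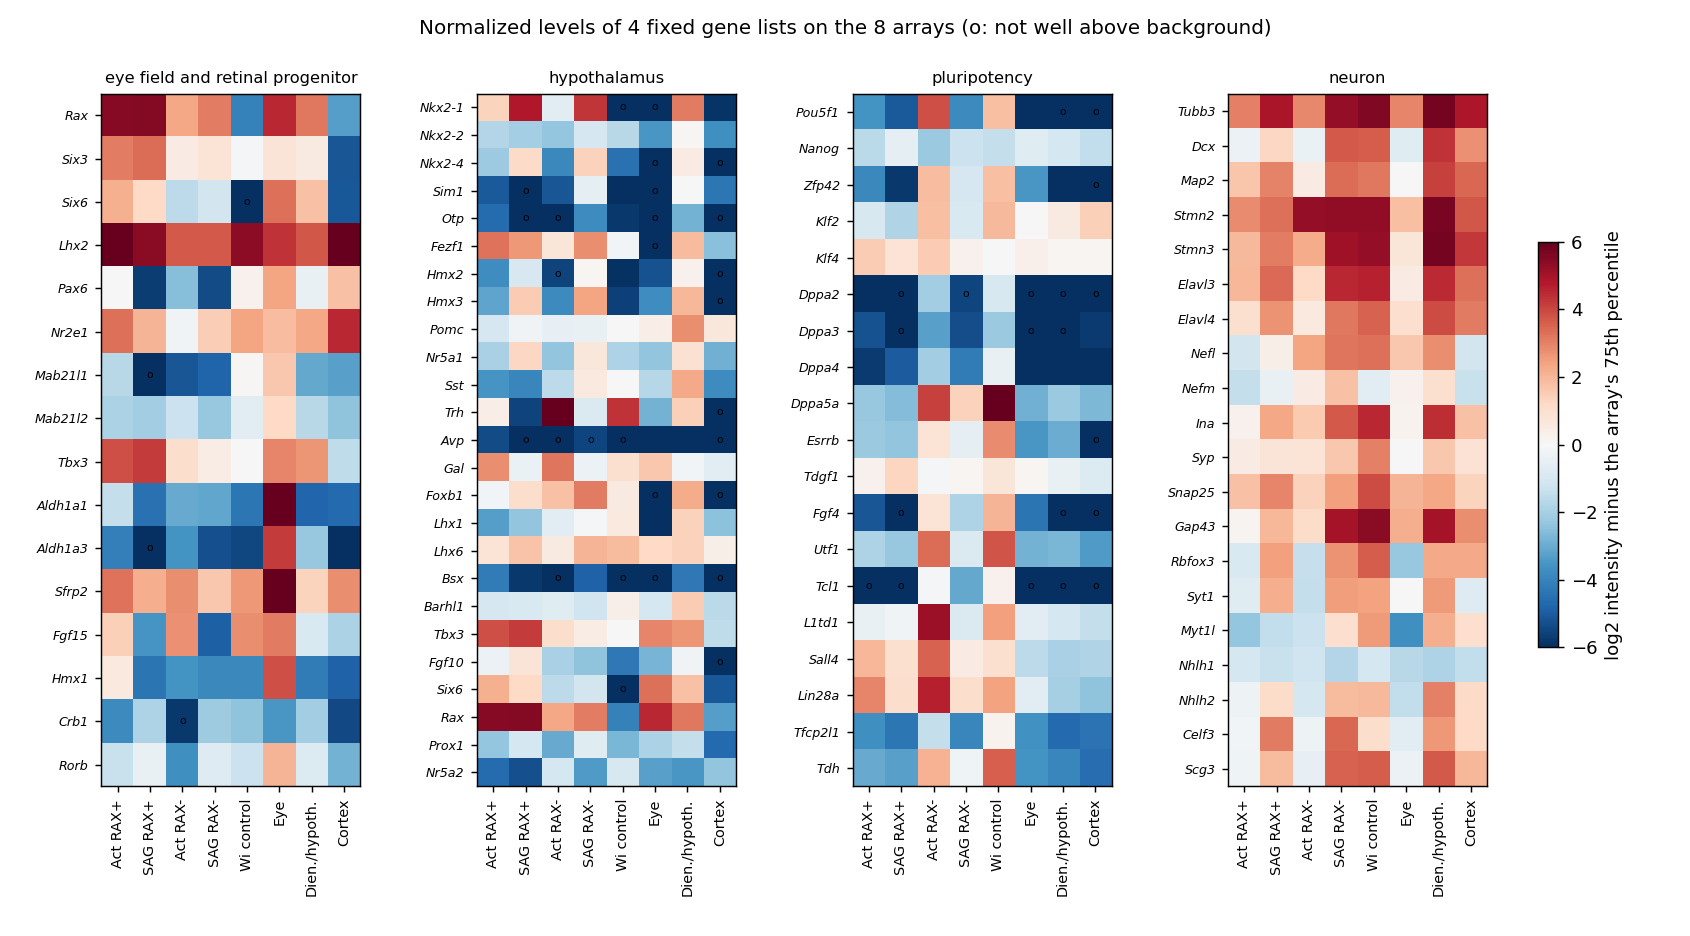
Normalized level (log2 intensity minus the 75th percentile of its array) of genes of the eye-field, hypothalamus, pluripotency and neuron lists on the 8 arrays. Circles mark genes that were not well above background on that array.

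Within RAX-positive cells, Activin/Nodal targets and part of the eye-field list were higher with activin than with SAG, along with genes of several other cell types. Lefty1, a feedback inhibitor of Nodal, was at least 425-fold higher (mm9 probe position chromosome 1, 182868137 to 182868196), Cer1 at least 20.03-fold, the activin-binding gene Fst 11.3-fold, Pmepa1 4.21-fold and Smad7 3.05-fold. That list had 12 higher and 2 lower of 19, a relative median of 1.33. Of the eye-field list, 10 of 17 were higher at a relative median of 0.93, among them Pax6 (50.9-fold), Fgf15 (30.9-fold), Aldh1a1 (8.09-fold), Lhx2 (2.25-fold) and Mab21l1 (at least 46.2-fold). Rax, Six3 and Six6 were not called. Hmx1 was 31.6-fold higher, and the anterior homeobox gene Hesx1 296-fold. The pigment epithelium list had a median normalized log2 level of -4.32 in these cells, 1.38 in eye and -4.05 in the Wi control. Its genes were higher with activin than with SAG, with the pigment enzyme gene Dct at 6.46-fold, Pmel at 4.36-fold and Mitf at 2.34-fold, and 8 of 12 of the list (1.05). Lists of unrelated cell types were also on the high side, with midbrain, hindbrain and spinal cord at 10 higher and 1 lower (1.16), mesoderm and endoderm at 8 and 0 (1.03), endothelium at 6 and 1 (0.80) and neural crest and mesenchyme at 7 and 2 (0.64), so that this was not particular to the eye. Dmrta2, of the dorsal telencephalon, was 46.4-fold higher. Cp was at least 387-fold higher, the secreted antagonist gene Grem1 119-fold, Mogat2 201-fold and Sytl2 at least 159.8-fold.

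The signal gene Shh and several hypothalamic factors were lower with activin than with SAG in the RAX-positive cells. Shh was 24.3-fold lower, its target Hhip 16.4-fold, Ptch1 4.22-fold, and the hypothalamic factors Hmx3 25.4-fold, Nkx2-1 11.2-fold and Nkx2-4 9.92-fold (mm9 probe position of Nkx2-1 chromosome 12, 57633119 to 57633178). The Hedgehog target list had 5 higher and 7 lower of 16, at -0.98. Of a list of 5 Hedgehog co-receptor and Gli factor genes, 3 were higher. These were the co-receptor genes Gas1 (5.26-fold) and Boc (8.73-fold) and the transcription factor gene Gli2 (at least 128-fold). In the hypothalamus list 6 were higher and 8 lower of 26, within the random lists, and Trh was 61.7-fold and Gal 9.30-fold higher. Prdm12 was 121-fold lower, although its 3 probes ran from -6.92 to -1.09 in log2, Foxd2 101-fold, Thsd4 53.7-fold, Gpr17 40.1-fold and Prdm13, of retinal and spinal interneurons, 51.1-fold. Neuron genes were lower, 15 of 20 at -1.69, with the splicing regulator Rbfox3 at 10.4-fold, the synaptic gene Syt1 at 7.34-fold and Tubb3 at 3.72-fold. The Notch list lay on the low side with few genes called, 1 lower and 3 higher of 15 at -0.71.

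Of 29078 genes detected, 5121 were higher with activin and 2071 lower, or 71.2% higher. Quantile scaling gave 3873 higher and 3185 lower, the authors' values 1763 and 1878, and normexp background 981 and 1299. The larger share of receptor genes above background given earlier concerns the activin array of this pair as well.

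Within RAX-negative cells, activin in place of SAG gave higher pluripotency and germ-layer genes. Fgf5 was at least 1439-fold higher, Pou5f1 206-fold, Eras at least 181-fold, L1td1 64.8-fold, Utf1 18.1-fold and Lin28a 12.0-fold, and 17 of 19 pluripotency genes were higher at a relative median of 2.70. Nanog was not called. Lefty1 was 843-fold higher, Lefty2 81.1-fold, Nodal 45.6-fold, and the Activin/Nodal target list had 13 of 19 higher at 1.67. Markers of endoderm and of the organizer, Cer1 (at least 176-fold), Gsc (117-fold) and Sox17 (at least 43.4-fold), were higher with 10 of 16 of the mesoderm and endoderm list. Fgf15 was 196-fold higher, Hesx1 333-fold, Trh 175-fold and Vrtn at least 197-fold, and the pigment epithelium list had 6 of 12 higher. The eye-field list had 5 higher and 3 lower of 17, within the random lists and with a direction that turned under normexp background, with Pax6 at 6.82-fold higher and Nr2e1 at 3.20-fold lower. The Wnt target list had 8 higher and 2 lower of 17 (0.87).

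Neuronal and hypothalamic genes were lower with activin in the RAX-negative cells. Hmx3 was 72.2-fold lower (mm9 probe position chromosome 7, 138688330 to 138688389), Hmx2 at least 51.1-fold, Nkx2-4 37.4-fold, Nkx2-1 30.9-fold, Sim1 23.9-fold and Sfta3-ps, beside Nkx2-1, 42.9-fold. The hypothalamus list had 14 of 25 lower against 4 higher (-1.38), and the ventral telencephalon list 14 of 16 (-3.09), with Lhx8 at 20.4-fold, Dlx1 at 10.4-fold and Dlx5 at 9.33-fold. Neurog3 was 83.3-fold lower (its 2 probes at -6.38 and -2.61 in log2), Neurog2 19.1-fold, Rbfox3 17.0-fold, Dcx 16.9-fold, Syt1 15.1-fold and Gap43 14.8-fold, and 16 of 20 neuron genes were lower at -2.76. The neurotransmitter list went along, 9 lower and 1 higher of 12, with Slc32a1 at 10.6-fold and Gad1 at 9.26-fold, and it shares Gad1 and Gad2 with the ventral telencephalon list. Gpr17 was at least 66.3-fold lower, Gjd2, a neuronal gap-junction gene, at least 55.4-fold, and Vtn 53.9-fold. The Notch list had 7 lower and 3 higher of 15, with its effector Hes5 at 5.60-fold, and shares Hes1, Hes5 and Notch1 with the pan-neural list. Of 25516 genes detected, 3558 were higher and 5023 lower, and median scaling gave 5934 higher and 3824 lower.

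Across both gates, 1285 genes were higher and 1156 lower with activin, against 404 and 359 for independent calls. The higher genes were led by Lefty1 and Hesx1 (mm9 probe position chromosome 14, 27815304 to 27815363), followed by the lipid enzyme gene Mogat2 (201-fold in RAX-positive and 202-fold in RAX-negative cells) and Trh. Spint1, a protease inhibitor gene of epithelia, was at least 41.3-fold and 60.6-fold higher, and the forebrain gene Zic5 37.5-fold and 70.02-fold. The lower genes were led by Prdm13, Gpr17, Foxd2 (101-fold and 39.6-fold) and the transporter gene Slc13a3 (47.3-fold and 30.9-fold), with Prdm12, Hmx3 and Mdga2 (at least 19.7-fold and at least 16.2-fold) after them. Another 813 genes were higher in the RAX-positive and lower in the RAX-negative cells, against 575 for independent calls, and 39 the other way round, against 252. The same limits hold here, since the activin RAX-positive array enters the 1285 and the 813, and the main setting alone was counted.

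For activin against SAG the limma model called 0 genes higher and 0 lower over all genes tested, with a smallest adjusted p of 0.324, 1909 higher and 1669 lower genes at an unadjusted p of 0.05, and between 0 and 1165 higher and 0 and 1641 lower over the other settings. Hesx1 had a log2 difference of 8.29 (standard error 0.30, adjusted p 0.324). Adjusted over the list alone, 16 neuron genes passed, 7 Activin/Nodal targets (among them Lefty1, Nodal, Cer1 and Fst), 7 of the hypothalamus list, 6 of the pigment epithelium list, 5 of the eye-field list (Pax6 and Fgf15 among them, and Crb1, which was lower by 3.98-fold in RAX-positive cells) and 0 of the pluripotency list, against 0 of each over all genes. Of the hypothalamus genes that passed, Trh was higher and Nkx2-1, Nkx2-4 and Hmx3 were lower with activin. Genes of the lens and surface ectoderm list and of the early retinal neuron list passed in that way too, so passing was not particular to the lists above.

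All 4 sorted populations had higher Rax, Six6 and Nkx2-1 and lower genes of the dorsal telencephalon than the Wi control. In RAX-positive cells after activin, Rax was 736-fold higher, Six6 at least 599-fold, Nkx2-1 at least 342-fold, Grem1 375-fold and Vax1 71.6-fold, while the cortical factors Neurod6, Emx1 and Tbr1 were at least 368-fold, 97.8-fold and 80.1-fold lower. After SAG the RAX-positive cells had Nkx2-1 at least 3832-fold, Sfta3-ps at least 2657-fold, Rax 755-fold and Hmx3 138-fold higher, and Trh 944-fold, Boc 83.9-fold and Gas1 15.9-fold lower. The RAX-negative cells after SAG had Nkx2-1 at least 2669-fold, Hmx3 249-fold and the basal forebrain gene Lhx8 224-fold higher. In RAX-negative cells after activin, Rax was 83.0-fold, Lefty1 52.2-fold and Pou5f1 4.16-fold higher. Pou5f1 was lower in the other 3 populations, by 42.3-fold in RAX-positive cells after activin, where Dppa5a was 552-fold lower. The pluripotency list was at -5.42 and -0.76 in RAX-positive and RAX-negative cells after activin, and at -5.30 and -3.41 after SAG. Its median normalized log2 level was highest on the Wi control array, at 1.80, against 1.54 in RAX-negative cells after activin. The dorsal telencephalon list had no gene called higher in any population, and 13, 15, 15 and 14 of 18 lower, for RAX-positive and RAX-negative cells after activin and then after SAG. The hypothalamus list had 14 higher and 7 lower of 26, and 10 and 4 of 23, after activin, and 12 and 7, and 15 and 4, of 25 after SAG, where the RAX-positive median of 0.45 was within the random lists. The eye-field list had 8 higher and 4 lower of 17 in RAX-positive cells after activin (0.62), and was within the random lists in the other populations.

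Neuron genes were lower than in the Wi control for 18 and 16 of 20 genes in the RAX-positive and RAX-negative cells after activin, for 11 in RAX-positive cells after SAG, and for 3, with 2 higher, in RAX-negative cells after SAG. Nfix, a factor of maturing neurons and glia, was 60.4-fold, 86.4-fold, 68.5-fold and 53.0-fold lower in the same order, and the urea transporter gene Slc14a2 211-fold, 276-fold, 347-fold and 336-fold, with its other probe between -5.60 and -5.28 in log2. The Wnt target list had 12 of 18 and 12 of 17 lower after SAG. The ventral telencephalon list stood out in RAX-negative cells after SAG, 10 higher and 1 lower of 16 (1.88). The control differs from the sorted cells in line, slide and added factor together, with no sort named for it, so these differences cannot be assigned to any of them. The counts were 8524 higher and 4334 lower, 4616 and 5581, 5717 and 5235, and 4556 and 4604, in the same order. For RAX-positive cells after activin, quantile scaling gave 6174 and 5554, the authors' values 3734 and 4241, and normexp background 2557 and 3117, and for RAX-negative cells after activin median scaling gave 6083 and 4711.

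The embryonic tissues differed in the genes known for each. Lens crystallin genes led the eye, with Cryaa 9805-fold and Cryge 3986-fold higher than in either other tissue, next to the retinal gene Aldh1a1 (2246-fold). In cortex Emx1 was 414-fold higher, Dmrt3 238-fold, Tbr1 64.8-fold, Eomes, of intermediate progenitors, 49.5-fold, and Neurod6 43.7-fold. Diencephalon/hypothalamus had Sfta3-ps 541-fold, Nkx2-1 498-fold, Foxb1 at least 369-fold, Foxa1 306-fold, Shh at least 262-fold, Gsx1 at least 232-fold and Gad1 152-fold higher. With a log2 difference of at least 2 over each other tissue, 723 genes formed the eye set, 297 the cortex set and 530 the diencephalon/hypothalamus set.

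The 3 tissue sets were followed in the sorted cells. With activin in place of SAG, the eye set was higher in RAX-positive cells for 264 and lower for 38 of 535 detected genes, a relative median of 0.72 (bootstrap 95% range 0.58 to 0.86), and in RAX-negative cells for 208 and 78 of 455, 0.74 (0.55 to 0.97). Under the alternatives each tissue set was drawn anew, so the values given for them here are not for the same genes. The eye set was then at 0.17 and 0.21 with normexp background, and its RAX-negative value at 0.0882 with no filter on dim genes. The diencephalon/hypothalamus set was lower with activin, at -0.92 (-1.07 to -0.76) in RAX-positive and -2.52 (-2.74 to -2.35) in RAX-negative cells. Of 434 of its genes detected there, 342 were lower and 21 higher. The cortex set was higher with activin in RAX-positive cells, 0.66 (0.39 to 0.78), but at 0.11 with normexp background, 0.21 with the authors' values, 0.26 with signal above background on both arrays and 0.25 with a tissue difference of 1, and at -0.18 in RAX-negative cells, where quantile scaling turned it to 0.23. Between gates, the diencephalon/hypothalamus set was lower in RAX-positive cells after SAG, -1.23 (-1.46 to -0.99), and at 0.48 after activin, where normexp background and the authors' values gave -0.05 and -0.07. The eye set was at -0.11 (-0.26 to 0.04) in the activin gate and -0.32 (-0.44 to -0.15) in the SAG gate. Random lists of like expression lay above the median of all genes in the activin gate, and there the eye set was below them, the diencephalon/hypothalamus set above and the cortex set within. Against the Wi control the diencephalon/hypothalamus set was at -1.57 and -1.85 in RAX-positive and RAX-negative cells after activin and at -0.80 and 0.34 after SAG, and so on the low side in 3 of the 4 populations. In the same order the eye set was at 0.04 (-0.18 to 0.30) and 0.23 (0.04 to 0.53) after activin and at -0.84 and -0.41 after SAG. That control is another line on another slide. With the top 100 genes of the eye, lens crystallins among them, the medians of the eye set between gates became 0.08 and 0.09.

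**Figure D3:**
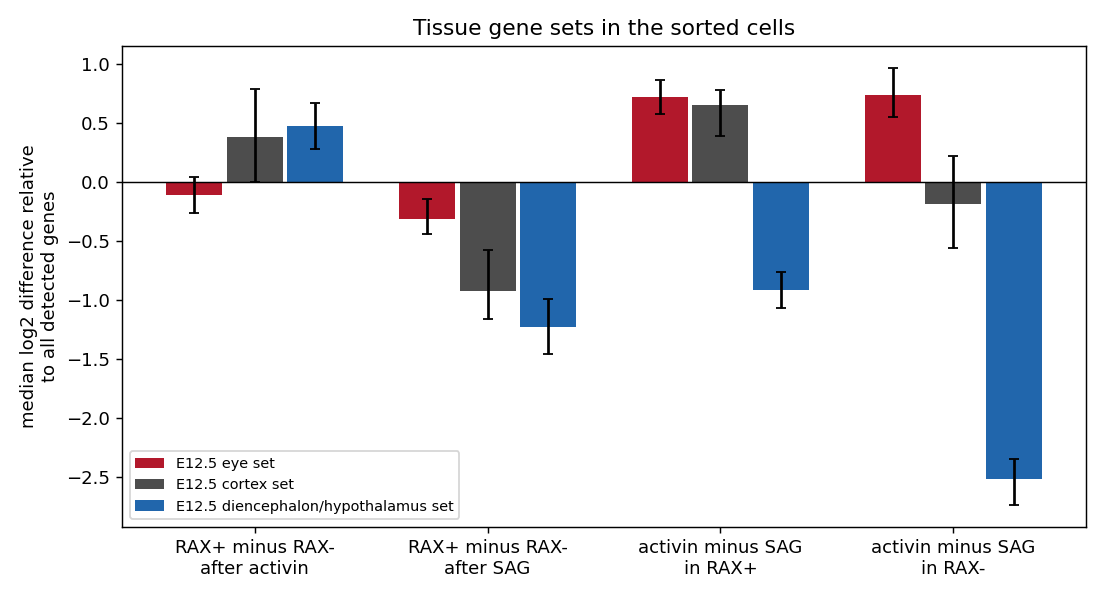
Median log2 difference of the eye, cortex and diencephalon/hypothalamus gene sets, relative to all detected genes, in the 4 comparisons of sorted cells. Bars are medians, and error bars are bootstrap 95% ranges over genes.

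Over the 4302 genes with a log2 range of at least 2 among tissues, centred profiles of both activin populations were closest to eye, with a Pearson r of 0.32 in RAX-positive and 0.33 in RAX-negative cells, against -0.33 and -0.30 for diencephalon/hypothalamus. The SAG populations were closest to diencephalon/hypothalamus, at 0.15 in RAX-positive and 0.38 in RAX-negative cells, against -0.09 and -0.29 for eye. For the Wi control the order depended on the measure, with a Pearson r of 0.17 for cortex and 0.12 for diencephalon/hypothalamus, and a Spearman correlation of 0.13 and 0.18. The difference of eye and diencephalon/hypothalamus r was 0.65 (bootstrap 95% range over genes 0.60 to 0.70) for RAX-positive cells after activin and 0.63 (0.58 to 0.68) for RAX-negative cells after activin. After SAG it was -0.24 (-0.29 to -0.18) and -0.68 (-0.73 to -0.62). Centring each gene over 5 cultures, 2 of them with activin and 2 with SAG, partly forces opposite signs on the treatments, so these values rank the cultures against each other alone. Without centring, each culture was closest to diencephalon/hypothalamus over these genes, from 0.76 in both activin populations to 0.87 in RAX-negative cells after SAG. Over all 31155 detected genes without centring, both activin populations were closest to cortex, at 0.937 in RAX-positive and 0.942 in RAX-negative cells, against 0.928 and 0.932 for diencephalon/hypothalamus and 0.926 and 0.935 for eye. With centring over all genes, RAX-negative cells after activin had a Pearson r of 0.14 for eye and 0.11 for cortex but a Spearman correlation of 0.0156 and 0.26, so their closeness to eye depends on the genes and the measure. Genes are not replicates, so these ranges describe the gene set and not a repeat of the cultures.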

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

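The tests of the split of the calls were chosen after the result was seen, except that of the receptor genes, which was written before its value. In RAX-positive cells after activin 78.4% of the called genes were higher. Signal near background on the RAX-negative array might give this and stays open. The share of 47.2% among genes well above background on both arrays decides nothing, as that filter removes any gene present in 1 gate alone. The share was 36.7% with normexp background and 48.2% with the authors' values, but 67.2% with median and 61.0% with quantile scaling. The excess of higher calls was thus absent with normexp background and the authors' values. Neither can tell signal near background from genes expressed at a low level in 1 gate. A raised low end on the RAX-positive array could give the excess. Its share of receptor genes was 1.81 times the highest share of the other arrays, which fits. The slide column stays open, since after SAG, where the columns were the same, 41.8% were higher but 54.9% with median scaling, between the limits of the test. Whether the RAX gate itself, as a biological cause, brings more expressed genes stays open too, because after SAG the RAX-positive array had 3.19 points more genes above background, which is between the limits written for the test.

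The tests of the pluripotency pattern were all chosen after the result was seen. Pluripotency genes were lower in RAX-positive than in RAX-negative cells after activin (relative median -3.85), and scaling or background may be set aside, since the weakest median over the 6 alternatives was -2.62. Undifferentiated cells in the RAX-negative gate could explain it, and the RAX sort would remove such cells from the RAX-positive gate alone. The pan-neural median of 0.49, higher in RAX-positive cells, met the limit of the test. A sort on Rax, a gene of the early eye field, could raise that list under each explanation, so the value cannot decide. Relative to the 75th percentile of its array, L1td1 was at 5.13 in RAX-negative and -0.47 in RAX-positive cells in log2, and Lin28a at 4.64 and 2.91. An earlier form of that test, the share of pluripotency genes that were lower (16 of 19), was also run, and was dropped after both values were seen because it repeats the pattern. That activin itself keeps these genes on is open, since the RAX-negative cells after activin were at -0.76 against the Wi control, but that control is another line on another slide with no sort named, and against SAG in the same line 17 of 19 were higher in RAX-negative cells, at 2.70.

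The tests of the hypoxia pattern were chosen after the result was seen, except that of the scaling. Of 15 detected genes of hypoxia and glycolysis, 13 were higher in every culture than in every tissue, and the fewest under any of the 6 alternatives was 9, by median scaling, which leaves a part for scaling open. Sorting stays open as well, since the Wi control, with no sort named, was 0.99 above the lowest of the sorted arrays, but is a single array of another line on another slide. Blood, vessel and mesenchyme cells in the tissues stay open too. The list exceeded the housekeeping genes by 1.30, past the limit written against this cause. Such cells may express housekeeping genes as well, and Pgk1 is in both lists, so that excess cannot decide it. Oxygen supply or medium in culture could be the biological cause, and no measurement here tests it.

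The remaining results are listed because a difference between 2 arrays had one sign in one setting and the opposite sign in the other, and none of these differences was tested. For single genes a bounded log2 difference of at least 2 in both settings was required, a limit set to keep their number short. Between RAX-positive and RAX-negative cells, the dorsal telencephalon list had a relative median of 0.79 after activin and -0.97 after SAG, a difference of 1.755. The hypothalamus list had 0.42 and -0.45, a difference of 0.87. For the list of thalamus and other diencephalon these were 0.59 and -0.87, a difference of 1.46. The diencephalon/hypothalamus tissue set had 0.48 and -1.23, a difference of 1.70. Irx1 had a log2 difference of 2.17 after activin and -3.45 after SAG, 5.62 apart, and Zic1 2.08 and -2.34, 4.42 apart. Mab21l1 had 3.46 and -2.66, 6.12 apart as measured, but after SAG its RAX-positive level was near background, where the bounded fold was at least 5.23-fold lower. Olig1 had 2.60 and -5.15, 7.75 apart, and Wnt7b 2.33 and -3.47, 5.80 apart.

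Between activin and SAG, the cholesterol synthesis list had a relative median of -0.54 in RAX-positive and 0.63 in RAX-negative cells, a difference of -1.17. Neurog2 had a log2 difference of 3.06 in RAX-positive and -4.26 in RAX-negative cells, 7.31 apart, and Nrn1 2.89 and -3.59, 6.48 apart. The oligodendrocyte-lineage genes Olig1 and Olig2 had 3.03 and -4.72, 7.75 apart, and 2.96 and -4.10, 7.06 apart. Wnt7b had 2.42 and -3.38, again 5.80 apart, and Zic1 2.29 and -2.13, again 4.42 apart, since both contrasts use the same 4 arrays.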

How the results depend on the processing

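The fixed gene lists named in the report kept their direction under every alternative where they lay apart from the random lists. The tissue sets did not all do so, and the turns counted below are theirs. Keeping outlier spots left 40 of 40 main results within the spread set for them, and limma with robust variance left its 4 counts at 0. Limma on all 8 arrays or at an adjusted p of 0.1 also gave 0, but neither could differ, since arrays alone in their group add no residual and the smallest adjusted p was 0.324. Over all alternatives 268 main results and 2012 list medians stayed within that spread, 146 and 91 moved, and 6 and 1 of those apart from the random lists turned in direction. A change of sign in a median within the random lists, as for the cortex set between gates after activin, is not in those counts. Of the differences of genes named in the text, 1059 stayed within that spread, 267 moved and none turned. The scaling moved the median of all genes in RAX-positive minus RAX-negative cells by -0.31 after activin and 0.17 after SAG for median scaling, by -0.18 and 0.01 for quantile scaling, and by -0.12 and -0.28 for normexp background. Fewer genes are expected with a larger limit of size, signal above background on both arrays and the top 100 genes by their construction, and for all other alternatives the cause was not tested. Depth limits the fold of genes near background, which is a lower bound. The slide as a block was not run, since all 4 sorted arrays were on slide 1. The limma model of gate and treatment is itself the gate contrast paired by treatment, with 1 residual degree of freedom.

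In RAX-positive cells after activin, the 6623 higher genes became 695 with normexp background, 4051 with quantile scaling, 1825 with the authors' values, 1288 with signal above background on both arrays, 3362 with a log2 difference of 2, 2160 with a difference over 3 errors and 2984 with the bounded difference. The 1824 lower genes became 1199 with normexp background and 818 with a log2 difference of 2. In RAX-positive cells after SAG, the 1983 higher genes became 451 with normexp background, 1275 with the authors' values, 1008 with signal above background on both arrays, 272 with a log2 difference of 2, 1120 with a difference over 3 errors and 1178 with the bounded difference. The 2761 lower genes became 1251 with normexp background, 1762 with signal above background on both arrays and 1228 with a log2 difference of 2. With activin against SAG in RAX-positive cells, the 5121 higher genes became 981 with normexp background, 1763 with the authors' values, 2479 with signal above background on both arrays, 1404 with a log2 difference of 2 and 3323 with a difference over 3 errors. The 2071 lower genes became 1299 with normexp background, 3185 with quantile scaling and 363 with a log2 difference of 2. With activin against SAG in RAX-negative cells, the 3558 higher genes became 2065 with normexp background, 5934 with median scaling and 1208 with a log2 difference of 2. The 5023 lower genes became 3009 with the authors' values, 2605 with signal above background on both arrays and 2379 with a log2 difference of 2. Against the Wi control, in RAX-positive cells after activin, the 8524 higher genes became 2557 with normexp background, 3734 with the authors' values, 4341 with signal above background on both arrays and 3708 with a log2 difference of 2. The 4334 lower genes became 1833 with a log2 difference of 2. Against the same control, in RAX-negative cells after activin, the 4616 higher genes became 3070 with normexp background and 1166 with a log2 difference of 2. The 5581 lower genes became 3200 with normexp background, 3559 with signal above background on both arrays and 2270 with a log2 difference of 2. Against it in RAX-positive cells after SAG, the 5717 higher genes became 2585 with normexp background, 3423 with the authors' values and 1983 with a log2 difference of 2. The 5235 lower genes became 3036 with normexp background and 2414 with a log2 difference of 2. Against it in RAX-negative cells after SAG, the 4556 higher genes became 2291 with normexp background, 2740 with the authors' values, 2977 with signal above background on both arrays and 1741 with a log2 difference of 2. The 4604 lower genes became 2147 with normexp background and 1728 with a log2 difference of 2.

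For the RAX gate over both treatments the limma model had 0 higher genes, against 2 with signal above background on all 4 arrays, 9 with a variance trend, 97 with normexp background and 176 with median scaling. It had 0 lower genes, against 41 with signal above background on all 4 arrays, 58 with a variance trend, 523 with normexp background and 465 with median scaling. For the activin against SAG over both gates the limma model had 0 higher genes, against 198 with signal above background on all 4 arrays, 283 with a variance trend, 1165 with normexp background and 751 with median scaling. It had 0 lower genes, against 128 with signal above background on all 4 arrays, 231 with a variance trend, 1641 with normexp background and 563 with median scaling. With signal above background on all 4 arrays 21187 genes were tested in place of 26473. The E12.5 eye set of 723 genes became 314 with normexp background, 370 with the authors' values, 313 with signal above background on both arrays and 2291 with a tissue difference of 1. The E12.5 cortex set of 297 genes became 80 with normexp background, 130 with the authors' values, 123 with signal above background on both arrays and 924 with a tissue difference of 1. The E12.5 diencephalon/hypothalamus set of 530 genes became 252 with normexp background, 324 with the authors' values, 269 with signal above background on both arrays and 1431 with a tissue difference of 1.

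The relative medians of the tissue sets moved as follows, with each set drawn anew under each alternative, so that its genes changed as well. Between gates after activin, the eye median of -0.11 became -0.30 with normexp background, -0.46 with quantile scaling, -0.49 with the authors' values, -0.48 with signal above background on both arrays, 0.11 with a tissue difference of 1 and 0.0827 with the top 100 genes. Cortex went from 0.38 to -0.0777 with signal above background on both arrays and -0.0776 with a tissue difference of 1. Diencephalon/hypothalamus went from 0.48 to -0.0545 with normexp background, 0.0894 with quantile scaling, -0.0668 with the authors' values and 0.0084 with signal above background on both arrays. Between gates after SAG, the eye median of -0.32 became -0.0954 with a tissue difference of 1 and 0.0903 with the top 100 genes. Cortex went from -0.93 to -0.32 with normexp background, -0.42 with median scaling, -0.29 with the authors' values, -0.49 with no filter on dim genes, -0.43 with signal above background on both arrays, 0.0563 with a tissue difference of 1 and -1.32 with the top 100 genes. Diencephalon/hypothalamus went from -1.23 to -0.96 with no filter on dim genes, -0.87 with a tissue difference of 1 and -2.23 with the top 100 genes. With activin against SAG in RAX-positive cells, the eye median of 0.72 became 0.17 with normexp background, 0.44 with the authors' values, 0.48 with signal above background on both arrays, 0.51 with a tissue difference of 1 and 0.97 with the top 100 genes. Cortex went from 0.66 to 0.11 with normexp background, 0.21 with the authors' values, 0.26 with signal above background on both arrays, 0.25 with a tissue difference of 1 and 0.96 with the top 100 genes. Diencephalon/hypothalamus went from -0.92 to -1.16 with quantile scaling, -0.71 with no filter on dim genes and -0.72 with a tissue difference of 1. With activin against SAG in RAX-negative cells, the eye median of 0.74 became 0.21 with normexp background, 1.07 with quantile scaling, 0.0882 with no filter on dim genes, 0.42 with a tissue difference of 1 and 1.31 with the top 100 genes. Cortex went from -0.18 to 0.23 with quantile scaling, 0.43 with a tissue difference of 1 and 0.23 with the top 100 genes. Diencephalon/hypothalamus went from -2.52 to -1.83 with normexp background, -2.24 with the authors' values, -2.28 with the mean over probes, -2.08 with no filter on dim genes, -2.02 with a tissue difference of 1 and -3.26 with the top 100 genes. In RAX-negative cells after SAG against the Wi control, the cortex median of -1.41 became 0.26 with no filter on dim genes. The eye minus diencephalon/hypothalamus correlation became, for activin RAX-positive cells (0.65), 0.74 with normexp background, 0.59 with quantile scaling, 0.78 with the authors' values and 0.77 with signal above background on both arrays. For activin RAX-negative cells (0.63) it was 0.83 with normexp background, 0.73 with quantile scaling, 0.92 with the authors' values, 0.92 with signal above background on both arrays and 0.52 with the Wi control left out. For SAG RAX-positive cells (-0.24) it was -0.30 with quantile scaling, -0.32 with the authors' values, -0.32 with signal above background on both arrays and -0.40 with the Wi control left out. For SAG RAX-negative cells (-0.68) it was -0.92 with normexp background, -0.75 with quantile scaling, -1.004 with the authors' values, -0.99 with signal above background on both arrays and -0.80 with the Wi control left out. For the Wi control (-0.35) it was -0.42 with normexp background and -0.28 with quantile scaling.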

Other observations

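Genes of cell types that enter the embryonic brain and eye from outside were low in the cultures. Of the erythroid list, 12 of 13 detected genes were lower in every culture than in every tissue, and of the microglia and macrophage list 10 of 12. The endothelium list had 7 of 11 and the neural crest and mesenchyme list 10 of 19 in that order. The other way round, 9 of 19 pluripotency genes, 9 of 15 genes of cholesterol synthesis and 7 of 15 genes of the dissociation and stress response were higher in every culture than in every tissue, and so were 7 of 14 housekeeping genes. No test belongs to these counts, and the tissues also differ from the cultures in strain and sex.

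Genes known to be imprinted were among the top-ranked differences from the Wi control, which is another ES line, but no list of such genes was tested. H19 was 159.6-fold higher in RAX-negative cells after activin and 89.8-fold after SAG, Plagl1 122-fold in RAX-positive cells after activin and 106-fold after SAG, and Peg13 64.5-fold and 176-fold in the RAX-positive and RAX-negative cells after SAG. The 7 probes of H19 ran from -0.09 to 6.49 in log2 in RAX-negative cells after SAG, and the 4 probes of Plagl1 from 0.42 to 7.202 in RAX-positive cells after activin. Among the stress genes, the early response genes Fos and Egr1 were 4.90-fold and 2.24-fold higher with activin than with SAG in RAX-positive cells and 2.86-fold and 2.03-fold in RAX-negative cells, with 7 and 6 of 15 genes of that list higher. The share of the eye set well above background was 73.2% in RAX-positive and 54.4% in RAX-negative cells after activin. The cortex set had 58.6% and 38.7%, the diencephalon/hypothalamus set 82.1% and 59.1%, and all genes other than receptor genes 84.7% and 67.9%, so the step was not particular to the eye set.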
